A study of Rattus norvegicus with 4 samples.

How the data were processed

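Total RNA was extracted with Trizol from 500 mg of frozen retroperitoneal adipose tissue per rat after 1 week of acclimatisation, and 100 ng was amplified and labelled for Affymetrix Rat Gene ST arrays, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 per row and array, and RMA is named in the submitters' processing notes. The software, its version, the probe-set level and the treatment of control probe sets are not given in the sources used here. The linear scale was read from the values, which ran from about 2 to over 10000 with a skewed distribution. RMA includes background correction and quantile normalization of probes, which makes arrays comparable in overall distribution and would reduce a shift common to most genes. The interquartile range of log2 values was nevertheless narrower for lean rat 2 (2.24) than for the other arrays (2.63 to 2.77).

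The intensities were transformed to log2 with no pseudocount, since all were above 0. Rows were named through the platform's annotation table: 15310 of 29214 rows had exactly 1 gene symbol, 323 had several and 13581 had none in that table. Of the rows with 1 symbol, 15279 matched a RefSeq gene of assembly GRCr8 by gene ID, and 0 symbols changed through this match. Rows with several symbols or none were left out of the main test, and no coordinates are given because the array's build is not named. For the 527 genes with more than 1 row, the row with the highest mean over all 4 arrays was kept, which gave 14506 genes, and no filter on dim genes was applied.

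Obese and lean rats were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with a mean-variance trend, over all 4 arrays without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The groups came from the sample titles and each sample is a separate rat. There were 28 gene lists of 698 entries, 612 of them measured, and a list needed at least 5 measured members. Lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 28 lists, with an estimated correlation and fry as alternatives. With an estimated correlation camera uses only the residual degrees of freedom, here 2, so few lists can pass whatever their correlation. The named genes are the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose higher mean is at or above the median gene, filled where too few pass with the largest differences at an unadjusted p under 0.05, a fixed set of metabolic and inflammatory genes, and up to 3 called members of each list or, where none was called, the 2 with the smallest p. Genes outside this rule were chosen after their values were seen. They are Itgb2, Mpeg1, Mrc1, Trem2, Cd163 and C1qa of the macrophage list and Cd3d, Cd3e and Cd3g of the lymphocyte list. The others are Ltf, Ngp, Ccr3, Prg2, Il5ra and Epx of the neutrophil and eosinophil lists and those in the closing observations. Lepr, part of the fixed set, was not analysed here because no row with a single symbol carried it.

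Groups, tests, lists, the naming rule and the alternatives were chosen before the data were examined. The alternatives were the rat number as a block, quantile normalization, median centring, other variance models, array weights, filters on dim genes, the mean of a gene's rows, all rows of the table, other thresholds and each rat left out in turn. The procedure was tested on simulated data drawn from the means and spread of these 14506 genes, with 200 genes changed in 20 simulations of 2 against 2 arrays. It recovered 3.51% of genes changed by 1 on the log2 scale, 80.1% of those changed by 2 and 98.5% of those changed by 3, and 5.16% of its calls were false. In these simulations, differences of about 1 were therefore mostly missed in single genes. The simulated genes varied independently, and unequal spread between the groups was not simulated. On the measured arrays the mean deviation from the group mean was 0.230 for the lean rats and 0.131 for the obese rats. The recovery and the share of false calls therefore hold for the simulated conditions and were not established for these arrays. In the same simulations, whose genes varied independently, camera called a list shifted by 1 in 100% of runs and 0.208% of unshifted lists, and genes that vary together were not simulated. Figures were drawn with matplotlib 3.10.9.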

Results

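Baseline gene expression was measured in retroperitoneal white adipose tissue, a visceral fat depot, of male rats of the WNIN/Ob strain, a rat strain with lean and obese phenotypes. There were 2 lean and 2 obese rats, all 4 months old and untreated, and each rat gave 1 sample hybridised to 1 Affymetrix Rat Gene ST array. The deposited intensities had a median of 41.0 for lean rat 1, 44.5 for lean rat 2, 39.9 for obese rat 1 and 39.9 for obese rat 2 over 29214 rows. Differences are given on the log2 scale as obese minus lean, over 14506 genes with a row of their own, and the small number of arrays limits their precision. The arrays of the obese rats resembled each other most, with a Pearson correlation across genes of 0.984, against 0.937 between the lean rats and 0.930 to 0.943 between a lean and an obese rat. Genes are not independent replicates, and these correlations are descriptions with no test.

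The comparison of the phenotypes asked which transcripts differ between obese and lean fat at baseline. Among the genes that rose were 12 of 31 macrophage genes, 5 of 19 genes of fatty acid synthesis, 2 of 17 of cholesterol synthesis and 6 of 26 of the cell cycle. These lists shifted upward by limma's camera test with a preset correlation. However, with an estimated correlation none was called (adjusted p = 0.394, 0.461, 0.394 and 0.394 with an estimated correlation). That setting leaves camera 2 residual degrees of freedom, so a lost call there says little for or against a shift. The largest rises were in Spp1, which encodes the secreted glycoprotein osteopontin, at 4.07 ± 0.43 (SE, n = 2 per group), Lyz2, the lysozyme of myeloid cells, at 3.92 ± 0.45, and Gpnmb, a glycoprotein of lipid-laden macrophages, at 3.90 ± 0.40. In linear terms these were 16.7-fold, 15.1-fold and 15.0-fold, with limma adjusted p of 0.011, 0.016 and 0.011. Next were Elovl6, which elongates newly made fatty acids (3.71), the myeloid receptor Clec5a (3.70), Slamf9 (3.67), the chemokine Ccl9 (3.66), the beta-glucan receptor Clec7a (3.58), the lysosomal acid lipase Lipa (3.51) and the cytochrome P450 gene Cyp4b1 (3.46). Fewer of the genes with a row of their own fell. Igfbp5, an insulin-like growth factor binding protein, fell by 2.70 on the log2 scale (SE 0.32, adjusted p = 0.018), and the organic cation transporter Slc22a3 fell by 2.45 (SE 0.36, adjusted p = 0.029). Also among the falls were Myoc (-1.93), the eosinophil chemokine Ccl24 (-1.92), Cpxm2 (-1.91), Pcp4l1 (-1.56) and the Wnt antagonist Frzb (-1.45). The call of Pcp4l1 was lost without obese rat 1 (-1.48, adjusted p = 0.063) and that of Frzb without obese rat 2 (-1.39, adjusted p = 0.073). Spetex2g had the most negative value of all genes tested, -3.72, but it belongs to a multigene family whose copies can share probes, so its identity is uncertain. In the obese rats it was at 2.74 and 3.64, near background, so the size of its fall is uncertain as well.

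**Figure D1:**
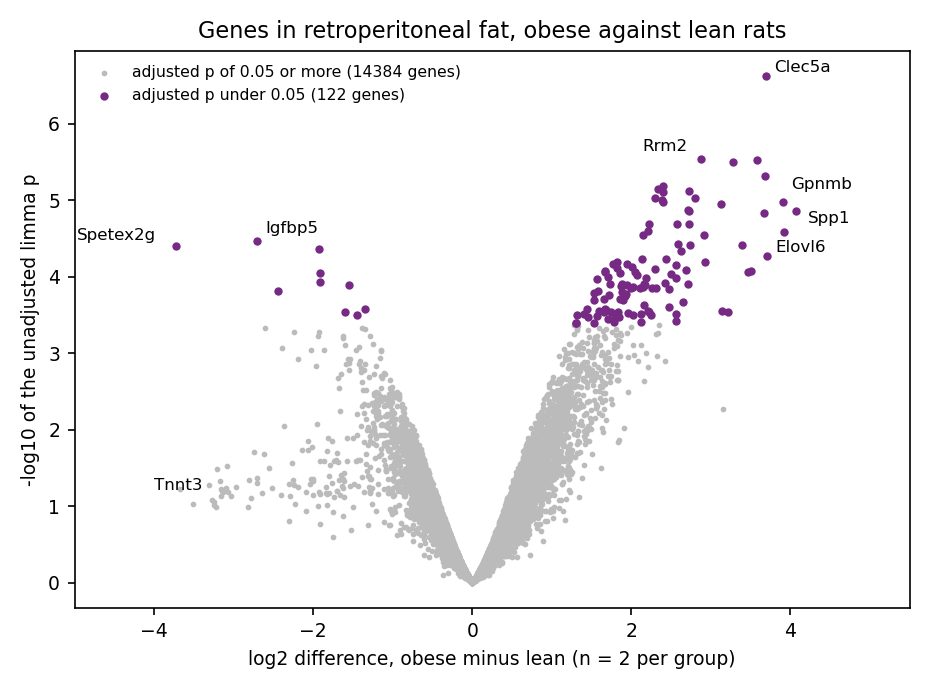
Each point is a gene, with the log2 difference (obese minus lean, 2 rats per group) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 122 genes past an adjusted p of 0.05 are coloured, and 112 of them lie to the right, whereas the muscle gene Tnnt3 lies far to the left without passing.

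In all, limma called 122 genes at an adjusted p under 0.05, of which 112 rose and 10 fell. Over all 29214 rows, with or without a single gene name, 185 were called, of which 89 rose and 96 fell (48.1% rose). Among the 122 genes the rises ranged from 1.30 to 4.07 and the falls from -1.35 to -3.72. At an unadjusted p under 0.05 there were 2214 genes, 1441 higher and 773 lower, against 725.3 expected by chance. Both obese rats lay above both lean rats in 26.4% of genes and below both in 21.3%, where chance gives 16.7% on average for each direction. Genes vary together, so how far these shares and the count of 2214 vary by chance is not known. Their excess is therefore no test of the phenotypes. With 2 rats against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.333, so the calls rest on the spread that limma shares among genes. The count was 1081 without lean rat 1, 477 without lean rat 2, 268 without obese rat 1 and 356 without obese rat 2, and the share of calls that rose was then 61.4%, 40.9%, 55.2% and 66.0%, against 91.8% of the 122. All 122 genes kept their sign each time, which is fixed for any gene whose groups do not overlap. Without a lean rat the spread came from the obese rats alone. Their mean deviation from the group mean was 0.131, against 0.230 for the lean rats. Without an obese rat limma replaced each gene's own spread by the trend shared among genes. A call gained with a rat left out is therefore weak support. With quantile normalization between arrays the count was 75, and of the named genes Acly, Ccr2, Cyp4b1, Cyp51, Fasn, Frzb, Mmp12, Plin2, Sqle and Top2a were no longer called, at adjusted p of 0.051 to 0.096. Centring arrays on their medians ended the calls of Acly, Cyp51, Fasn, Mmp12 and Slc22a3.

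Of 31 macrophage genes measured, 12 rose, none fell and 19 did not pass (23 passed when adjusted over the list alone). The list's median difference was 1.61, and both obese rats lay above both lean rats for 25 members. Beside Spp1, Lyz2 and Gpnmb, the called members included Itgb2 (3.39) and Mpeg1 (2.71). Cd68, a lysosomal protein of macrophages, was at 2.04 ± 0.41 with an adjusted p of 0.075, and ran from 1.48 to 2.59 with a rat left out. Members differed widely, since Mrc1 was at 1.61 and Trem2 at 1.85 but Cd163 was at -0.05 and C1qa at 0.27, none of these past the threshold. By limma's camera test with a preset correlation the list stood above other genes (adjusted p = 3.92e-20), but not with an estimated correlation (adjusted p = 0.394 with an estimated correlation). The list of inflammatory mediators was not called (median 0.01, camera adjusted p = 0.223), but without lean rat 2 it was called higher (median 0.28, adjusted p = 0.011), and without lean rat 1 camera's direction turned (median 0.014, adjusted p = 0.933). Of its 29 members, 2 rose, the chemokine receptor Ccr2 (2.26) and the interleukin-1 receptor antagonist Il1rn (2.42). Tnf was at -0.09 ± 0.28 and Ccl2 at -0.59 ± 0.54, and both values were above 0 without lean rat 2, where Ccl2 was at 0.28 and Tnf at 0.22. Tnf was also above 0 when arrays were centred on their medians (0.013).

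Of 19 genes of de novo lipogenesis, 5 rose, none fell and 14 did not pass (16 passed when adjusted over the list alone), with a median of 1.37. By camera the list stood above other genes (adjusted p = 3.40e-11), but not with an estimated correlation (adjusted p = 0.461 with an estimated correlation). Fasn, the fatty acid synthase, rose by 2.12 ± 0.35 (adjusted p = 0.042), Scd, the stearoyl-CoA desaturase, by 2.18 ± 0.31 (adjusted p = 0.027) and Acly, which supplies cytosolic acetyl-CoA, by 2.21 ± 0.36 (adjusted p = 0.041). The call of Fasn was lost without lean rat 2 (adjusted p = 0.050). Of 17 cholesterol synthesis genes, 2 rose, Sqle (1.88), an early oxygen-dependent enzyme of sterol synthesis, and Cyp51 (1.78), the lanosterol demethylase, and 14 passed when adjusted over the list alone. The median of the cholesterol list was 1.26, and both obese rats exceeded both lean rats for all 17 members. Camera gave an adjusted p of 3.25e-12 for this list, and adjusted p = 0.394 with an estimated correlation. Among 21 genes of triglyceride synthesis and fatty acid uptake, the lipid droplet protein gene Plin2 rose (2.47) and no other member passed (5 adjusted over the list alone). That list's median was 0.60, with a camera adjusted p of 4.27e-06 and adjusted p = 0.394 with an estimated correlation.

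**Figure D2:**
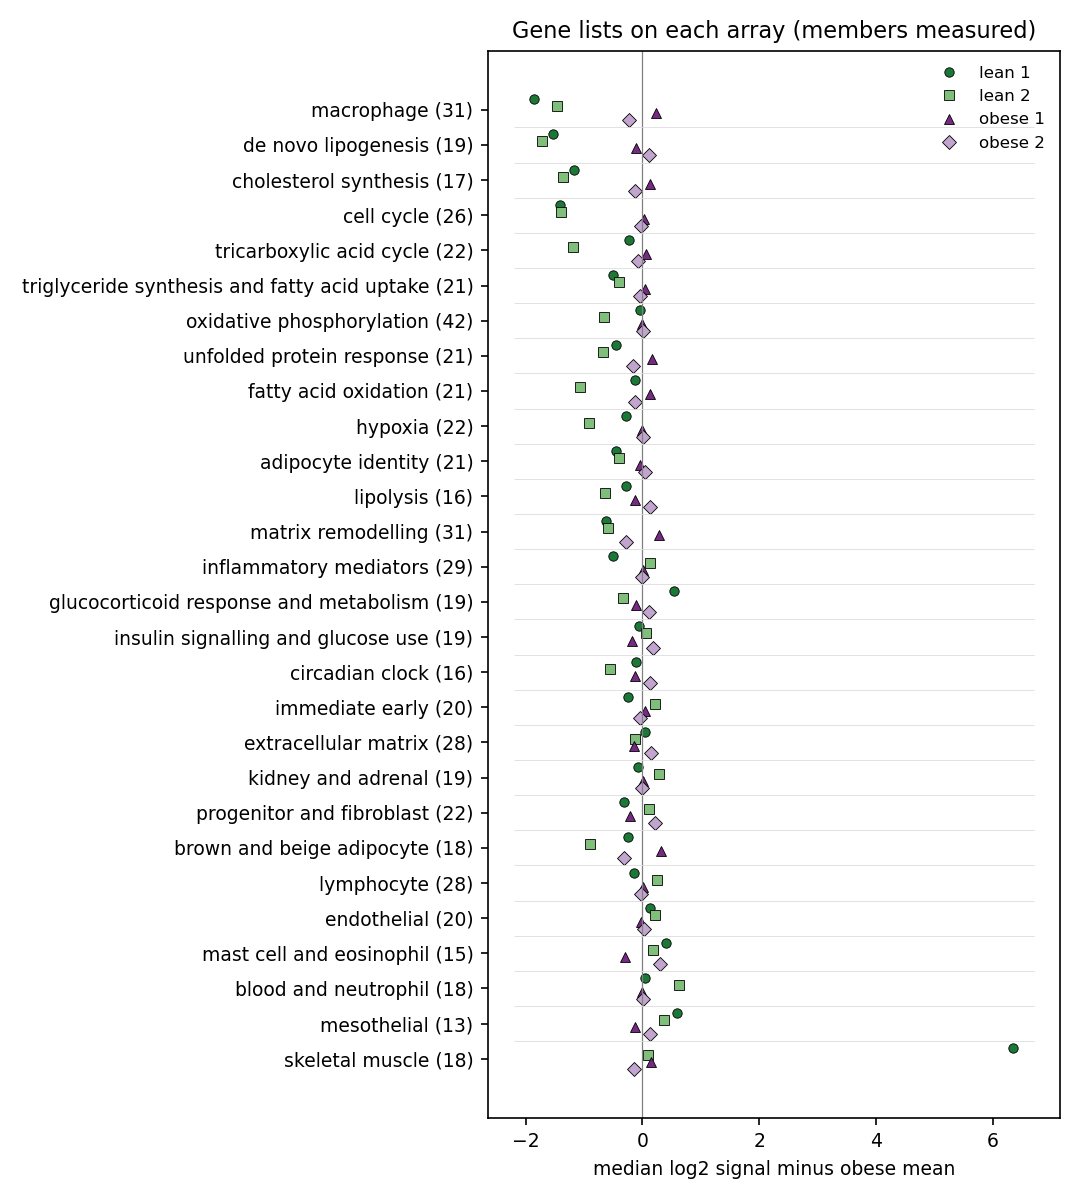
Each row is a gene list with the number of members measured in brackets, and each symbol is the median log2 signal of the list in 1 rat minus the mean of the medians of the obese rats. Both lean rats lie to the left for the macrophage, lipogenesis, cholesterol and cell cycle lists, and lean rat 1 lies far to the right for skeletal muscle.

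Of 26 cell cycle genes, 6 rose, none fell and 20 did not pass (22 passed when adjusted over the list alone), and the median was 1.05. The camera adjusted p was 3.92e-20, and adjusted p = 0.394 with an estimated correlation. Rrm2, a ribonucleotide reductase subunit, rose by 2.87 ± 0.25 (adjusted p = 0.011), the topoisomerase Top2a by 2.69 ± 0.36 (adjusted p = 0.025) and the spindle gene Nusap1 by 1.95 ± 0.26 (adjusted p = 0.025). By fry, which asks whether the genes of a list move on balance in the same direction, the cell cycle list and the endothelial list each had an adjusted p of 0.034, and no other list passed.

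Lep, the gene of the hormone leptin, was at 1.56 ± 0.41 with both obese rats above both lean rats, and its adjusted p was 0.145. Without lean rat 2 it passed (2.06, adjusted p = 0.036). Adipoq, the adiponectin gene, was at 0.15 ± 0.31 and Pparg, the main adipogenic transcription factor, at 0.18 ± 0.31, and both were below 0 with quantile normalization (-0.05 and -0.0047). With a rat left out Adipoq ran from 0.0028 to 0.30 and Pparg from 0.042 to 0.33. Lpl was at 0.32 ± 0.32 (0.083 to 0.56 with a rat left out), the insulin-responsive glucose transporter Slc2a4 at 0.44 ± 0.34 (0.079 to 0.80) and Hsd11b1, which regenerates active glucocorticoid, at 0.57 ± 0.27 (adjusted p = 0.360). Ucp1, the uncoupling protein of brown fat, was at -0.89 ± 0.69, at 0.06 without lean rat 1 and at -1.76 without obese rat 1. Adrb3, the adrenergic receptor of adipocytes, was at -1.60 ± 0.30 with an adjusted p of 0.067, and ran from -1.81 to -1.39 with a rat left out. None of the 21 adipocyte identity genes passed (median 0.25, camera adjusted p = 0.261, 1 lower adjusted over the list alone), and the median was 0.083 without obese rat 2 and 0.39 without obese rat 1. None of 16 lipolysis genes passed (median 0.21, adjusted p = 0.456), where adjustment over the list alone gave 2 higher and 1 lower and Mgll, the monoglyceride lipase, was at 1.28. That median was 0.13 without obese rat 2, 0.33 without lean rat 2 and 0.35 without obese rat 1. Camera's direction for both lists turned to lower with quantile normalization.

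No member of the mitochondrial lists passed, and camera called the lists higher only with a preset correlation. The tricarboxylic acid cycle list (22 genes, median 0.75) had an adjusted p of 1.53e-05, the oxidative phosphorylation list (42 genes, median 0.54) also 1.53e-05, and the fatty acid oxidation list (21 genes, median 0.44) 0.013. With an estimated correlation these were adjusted p = 0.698, adjusted p = 0.556 and adjusted p = 0.706. Dlat and Mdh1 had the smallest p of the cycle genes, at 1.49 and 1.04 (Dlat passed without lean rat 1, at 2.02 with an adjusted p of 0.030, and was at 0.95 without lean rat 2), Cox7b was at 0.75, Ndufb8 at 0.72, Decr1 at 0.98 and Etfb at 0.85. Lean rat 1 exceeded lean rat 2 by a median of 0.94 for the cycle list, 0.37 for oxidative phosphorylation and 0.71 for fatty acid oxidation, and by a median of 5.77 for skeletal muscle genes. Without lean rat 1 the medians were 1.28 for the cycle list (adjusted p = 9.56e-09), 0.77 for oxidative phosphorylation and 0.82 for fatty acid oxidation. Without lean rat 2 they were 0.33 (adjusted p = 0.216), 0.30 (adjusted p = 0.027) and 0.10 (adjusted p = 0.995), and camera's direction for fatty acid oxidation turned. Fatty acid oxidation was also not called without obese rat 1 (adjusted p = 0.093).

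Genes of the unfolded protein response had a median of 0.51 (21 genes, camera adjusted p = 0.0016). That list's call was lost with an estimated correlation (adjusted p = 0.485) and without obese rat 1 (median 0.39, adjusted p = 0.079). Atf3 was at 1.41 and Sdf2l1 at 1.31, and none passed singly. Without obese rat 2 these genes were at 2.03 and 1.62, and without obese rat 1 Atf3 was at 0.79. The matrix remodelling list had a median of 0.21 (31 genes, adjusted p = 0.0062, adjusted p = 0.394 with an estimated correlation, and a median of 0.37 without lean rat 1), and its called member was the macrophage elastase Mmp12 (3.21 ± 0.52, 3 passed adjusted over the list alone). Mmp12 was at 3.80 and 4.07 in the lean rats, near background, so the size of its rise is uncertain. The call of Mmp12 was lost without lean rat 1 (adjusted p = 0.051) and without lean rat 2 (adjusted p = 0.065), with a robust variance model (adjusted p = 0.130), without the variance trend (adjusted p = 0.055) and without the lowest 25% of genes (adjusted p = 0.052). The extracellular matrix list was not called (28 genes, none passing, adjusted p = 0.456). Its median was -0.03 whereas its mean was 0.16 and camera's direction was upward, and camera's direction turned with quantile normalization. The median was 0.098 without lean rat 2. Col1a1, the main fibrillar collagen chain, was at -0.43 ± 0.32 (-0.68 to -0.18 with a rat left out), Bgn at 1.24 and Serpinh1 at 1.16, and Bgn passed without lean rat 1 (1.47, adjusted p = 0.046). Progenitor and fibroblast genes had a median of -0.08 (adjusted p = 0.587), with Thy1 at 1.35 and Igf1 at -1.22, and Thy1 passed without lean rat 1 (1.37, adjusted p = 0.041).

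Lists of other cell types were measured as well. Skeletal muscle genes had a median of -3.15 (18 genes, camera adjusted p = 3.37e-07, and adjusted p = 0.646 with an estimated correlation), and none passed. Their median log2 signal was 11.7 in lean rat 1 but 5.46 in lean rat 2, 5.51 in obese rat 1 and 5.23 in obese rat 2, and without lean rat 1 the difference was -0.12 (adjusted p = 0.293). Tnnt3 (-3.21) and Ryr1 (-2.01) are members, and the muscle gene Mybpc1 was at -3.18, all with an adjusted p over the threshold. Without lean rat 2 these 3 genes were at -5.63, -3.64 and -5.81, and without lean rat 1 at -0.79, -0.37 and -0.54. Mesothelial genes had a median of -0.31 (13 genes, adjusted p = 0.0010, and adjusted p = 0.394 with an estimated correlation), with Gpm6a at -1.01 and Krt18 at -1.24. The mesothelial median was -0.47 without lean rat 1 and -0.50 without obese rat 2, and both genes passed without lean rat 2 (-1.32, adjusted p = 0.029, and -1.81, adjusted p = 0.010), while Krt18 was at -0.67 without lean rat 1. Endothelial genes had a median of -0.20 (20 genes, adjusted p = 0.040, and adjusted p = 0.461 with an estimated correlation), with Emcn at -1.19 (passing without lean rat 1, -1.52, adjusted p = 0.036) and Plvap at -0.89, and the list's call was lost without lean rat 1, obese rat 1 or obese rat 2 (adjusted p = 0.215, 0.093 and 0.169). Blood and neutrophil genes had a median of -0.28 (18 genes, adjusted p = 0.012, and adjusted p = 0.639 with an estimated correlation), with the beta-globin gene Hbb-b1 at -1.82 and Alas2 at -1.58. Without obese rat 1 these genes were at -2.66 and -2.29, and without obese rat 2 they were at -0.98 and -0.87. The neutrophil members lay between -0.31 (Ltf) and 0.18 (Ngp), so the larger falls of this list were not in neutrophil genes. The list's call was lost without lean rat 2 (median -0.11, adjusted p = 0.376) and without obese rat 2 (median -0.25, adjusted p = 0.065). Mast cell and eosinophil genes had a median of -0.26 (15 genes, adjusted p = 0.012, and adjusted p = 0.556 with an estimated correlation), with Gata2 and Mcpt1 both at -0.76 (Gata2 from -1.03 to -0.49 with a rat left out), and were not called without lean rat 2 (median -0.28, adjusted p = 0.059) or obese rat 1 (median -0.086, adjusted p = 0.186), while without obese rat 2 the median was -0.58. Mcpt1 lay between 1.96 and 3.09 on the arrays, below the median of olfactory and vomeronasal receptor genes near background on each, so its difference carries little information. The eosinophil members Ccr3, Prg2, Il5ra and Epx were at -0.19, -0.11, -0.00098 and 0.10, so a fall is not shown for eosinophil genes. Of 28 lymphocyte genes, Cd4 was at 1.83 (2.36 without obese rat 2), Blnk at 0.84, and Cd3d, Cd3e and Cd3g at -0.02, 0.02 and 0.34. Lymphocyte genes were not called as a list and none passed singly (median -0.14, camera adjusted p = 0.168). They were called lower without lean rat 1 (median -0.43, adjusted p = 0.024) and without obese rat 1 (median -0.22, adjusted p = 0.039), and the median was 0.084 without lean rat 2.

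**Figure D3:**
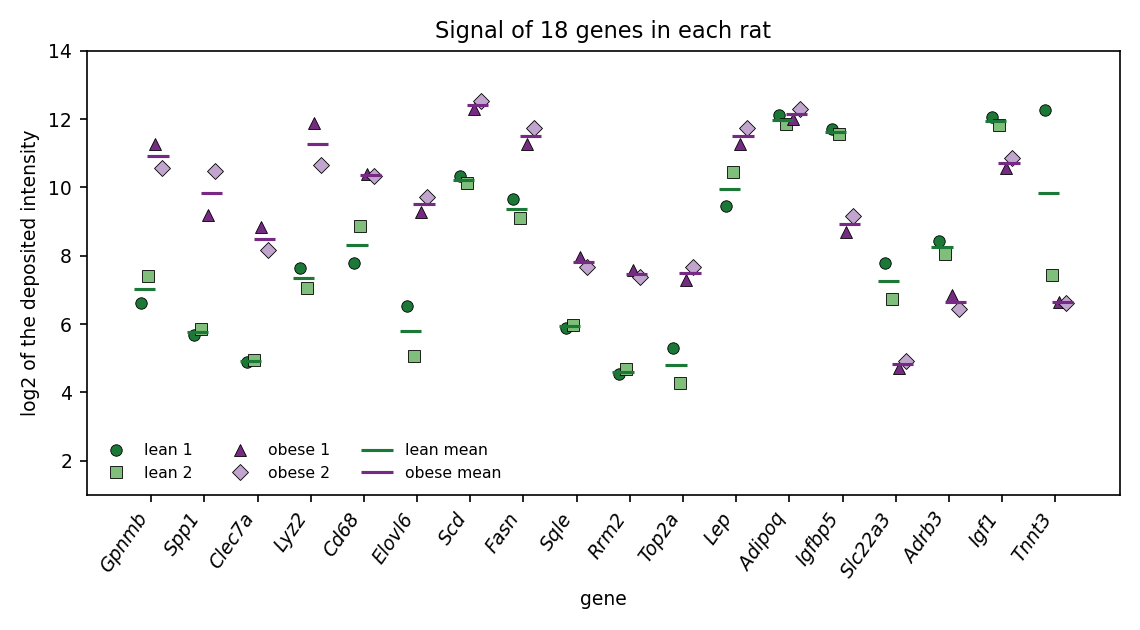
Log2 of the deposited intensity of 18 of the named genes in each rat, with a horizontal line at the mean of each group (2 rats each). The obese rats lie above the lean rats for Gpnmb, Spp1 and Rrm2 and below them for Igfbp5, the symbols of Adipoq overlap, and Tnnt3 is high in lean rat 1 alone.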

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

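All of the 122 called genes kept their direction in each setting of the fit over single genes. With the filters 117 and 78 of them were tested and kept it. This is little evidence of stability. The block, the variance models and the array weights leave each log2 difference unchanged. Leaving out a rat cannot turn a gene whose groups do not overlap. The number of calls was not stable. It was 327 with the rat number as a replicate block (254 rose), 75 with quantile normalization (68 of the 122 kept), 262 with a robust variance model, 66 without the lower 50% of genes by mean, 185 over all rows of the table (89 rose and 96 fell), 301 at an adjusted p under 0.1 and 878 at an unadjusted p under 0.05 with a difference of at least 1. Fewer genes were tested in the filtered setting, and the looser thresholds admit more genes of the same fit. Of the 185 calls over all rows, 111 were rows without a single gene name. For the block, quantile normalization and the robust variance model the cause was not tested. The remaining settings gave 101 to 171 calls. Leaving out each rat in turn gave 268 to 1081 calls, with the lone rat of a group assumed to vary like the other group. Without an obese rat the spread left is that between the lean rats, but limma then gave each gene the spread of the trend alone. A gene's own difference between the lean rats did not enter. The rat numbers share only a number (correlation of deviations 0.020 over 2 pairs), so the block is no paired analysis. The share of calls that rose was 77.7% under the block, against 91.8%. Of the 33 called genes among the named ones, 10 lost their call with quantile normalization and 5 with median centring, which moved the median of all genes to 0.099.

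Camera called 15 lists, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and fry called 2. With an estimated correlation the test has 2 residual degrees of freedom, so the lost calls cannot be put down to correlation alone. The mesothelial list had an estimated correlation of -0.038, below the preset 0.01, and still lost its call (unadjusted camera p 0.00032 and then 0.063). The skeletal muscle list had 0.995, so the preset value was too low for some lists. With quantile normalization the calls of fatty acid oxidation, mast cell, blood and matrix remodelling genes were lost, with the block that of endothelial genes, and with filters those of fatty acid oxidation and, for the lower 50%, matrix remodelling. Filters brought calls of lymphocyte (adjusted p = 0.039), progenitor (0.047) and immediate early genes (0.033). Without the lower 50% of genes the lymphocyte, mast cell and eosinophil, mesothelial and kidney and adrenal lists had fewer than 5 members and were not tested. Settings of eBayes do not enter camera and were not run for lists. Directions are camera's, so a median need not change sign with them. Direction turned with quantile normalization for adipocyte identity (median 0.050), lipolysis (0.081), extracellular matrix (-0.11), kidney and adrenal (0.13), insulin signalling (-0.067) and glucocorticoid response (-0.17). Without the lowest 25% of genes it turned for extracellular matrix (-0.034), insulin signalling (-0.00045) and glucocorticoid response (0.0024), and without the lower 50% for adipocyte identity and lipolysis (0.25 each), extracellular matrix (-0.034), insulin signalling (-0.0025) and glucocorticoid response (0.0024). It turned for glucocorticoid response with median centring (0.10) and for immediate early genes with fry (-0.028). Among genes, Adipoq (-0.053) and Pparg (-0.0047) turned with quantile normalization and Tnf (0.013) with median centring. For these, the cause was not tested.

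With each rat left out in turn, medians ranged from 0.10 to 0.82 for fatty acid oxidation, -0.11 to 0.17 for brown and beige genes, 0.014 to 0.28 for inflammatory mediators, -0.13 to 0.10 for progenitors, -0.24 to 0.081 for kidney and adrenal, -0.18 to 0.27 for insulin signalling, -0.12 to 0.23 for glucocorticoid response, 0.050 to 0.40 for hypoxia, -0.22 to 0.13 for the circadian clock and -0.30 to 0.083 for immediate early genes, and each of these turned direction at least once. Inflammatory mediators were called without lean rat 2 (adjusted p = 0.011) and hypoxia without lean rat 1 (adjusted p = 0.028). Ccl2 ranged from -1.47 to 0.28, Tnf from -0.39 to 0.22 and Ucp1 from -1.85 to 0.062. Over the upper 50% of genes the array correlations were 0.838 between the lean rats, 0.953 between the obese rats and 0.806 to 0.855 between groups, a set without the dim genes that widen the range. Genes near the lowest signals carry little information above background.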

Other observations

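Several lists fixed before the data were examined were not called by camera but held a called gene. Otop1, a proton channel gene placed among brown and beige adipocyte genes, rose by 2.80 ± 0.28 (adjusted p = 0.011), while that list of 18 genes had a median of -0.13, a mean of 0.12 and a camera adjusted p of 0.844. Star, which delivers cholesterol to mitochondria for steroid synthesis, rose by 2.04 ± 0.28 (adjusted p = 0.025), while the kidney and adrenal list had a median of -0.06 (adjusted p = 0.456). Rgs1, a regulator of G protein signalling in immune cells, rose by 2.74 ± 0.33 (adjusted p = 0.018), while the immediate early list had a median of -0.03, a mean of 0.02 and an adjusted p of 0.739. No member passed among 19 genes of insulin signalling and glucose use (median -0.00045, mean 0.06, adjusted p = 0.896), where Rapgef3 was at -0.61 and Slc2a1 at 0.61 (0.34 to 0.87 with a rat left out), or among 19 glucocorticoid genes (median 0.0024, adjusted p = 0.955), where the metallothioneins Mt2A and Mt1 were at 1.53 and 1.25 (Mt2A passed without lean rat 2, 1.97, adjusted p = 0.037). Mt1 ran from 0.67 to 1.82 with a rat left out. Hypoxia genes had a median of 0.30 (adjusted p = 0.218), with Eno1 at 0.88 (0.57 to 1.20 with a rat left out) and Pdk1 at 0.80, and clock genes a median of -0.0037 (adjusted p = 0.587), with Bhlhe41 at 1.28 (passing without lean rat 1, 1.32, adjusted p = 0.042) and Nr1d1 at -1.09 (-1.64 to -0.54 with a rat left out).

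The tests of the lean phenotype, of muscle RNA as a source of the tricarboxylic acid cycle values, of the share of adipocytes, of dilution and of repeated sequences were chosen only after the result they measure was seen.

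Muscle and tricarboxylic acid cycle transcripts were higher in lean rat 1 than in lean rat 2. A second list of 32 muscle genes exceeded the mean of the other arrays in lean rat 1 by a median of 3.26 (interquartile range 2.29 to 4.54), in line with skeletal muscle tissue in that sample, where Acta1 was at 12.9 and Ckm at 12.0. The lean phenotype is argued against, since the first muscle list in lean rat 2 exceeded the obese mean by 0.12, against 6.02 in lean rat 1. For the cycle genes, a narrower range of the lean rat 2 array is argued against by a gap of 0.94 between the lean rats, above the 95th percentile of 0.54 in 10000 lists matched on brightness. Muscle RNA may raise the cycle genes in lean rat 1, but their level there was -0.33 relative to the obese mean. The 95% bootstrap interval was -0.58 to -0.05. It was drawn over the genes of the list, so it holds no variation between rats. This met the bound first set against the explanation. That bound was set aside after the value was seen because obese levels can differ by phenotype, so the question stays open.

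Of 31 macrophage genes, 12 rose, and both obese rats exceeded both lean rats for 25, while the list was not called with an estimated correlation (adjusted p = 0.394 with an estimated correlation). A smaller share of adipocytes is argued against, since endothelial genes had a median of -0.20 and progenitor genes of -0.08, against 1.61 for macrophage genes. Dilution by muscle RNA in lean rat 1 is argued against by a macrophage median of 1.48 relative to lean rat 2 alone. An even rise of all macrophage transcripts is argued against by 11 genes of tissue-resident macrophages, whose median was -0.23, with Folr2 (1.83) as an exception. The 95% bootstrap interval of -0.36 to 0.28 was drawn over genes and holds no variation between rats. However, Cd209a and Vsig4 are near the lowest signals. Several of the others, such as Selenop, Gas6 and Igf1r, are also expressed by other cells. A difference between the phenotypes in the number or state of macrophages stays open as untested, and cell numbers were not measured.

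Over all rows of the table, 91 rows without a single gene name fell and 20 rose. The rows that fell had a median of -3.49, with a median log2 signal of 6.90 in lean rat 1, 7.80 in lean rat 2, 3.63 in obese rat 1 and 3.96 in obese rat 2. A higher background in the lean arrays is argued against for a fall of this size by 1238 olfactory and vomeronasal receptor genes, which lie near background. Their median difference was -0.38. Their median signal was nevertheless 3.38 in lean rat 1 and 3.85 in lean rat 2, against 3.16 in each obese rat. Signals near background were thus higher in lean rat 2, which may bear on lists of dim genes and was not tested there. Whether repeated sequences were counted several times cannot be told apart from separate transcripts, because the 91 rows held 80 distinct profiles when rows with values equal to 2 decimals on all 4 arrays were counted as 1, between the bounds set for either reading. The rows' identity is not given in the sources used here, and a difference between the phenotypes stays open as untested.

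Whether chance assignment of rats to groups gives as many calls could not be settled, since the 4 rats allow only 3 splits into 2 and 2, too few for a share under 0.05. The real split was the 1 split with as many genes, with 122, and the highest of the others gave 0.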
